A study of Mus musculus with 47 samples.

How the data were processed

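Poly(A) RNA of the gastrocnemius, a calf muscle of mixed but mostly fast fibres, was sequenced from mice of 3 inbred strains, both sexes and 2 diets. C57BL/6J is the common laboratory strain, CAST/EiJ is derived from wild mice of the subspecies castaneus, and NZO/HlLtJ is an obese strain used as a model of type 2 diabetes. Per the labels, mice entered a control diet (10% fat+fiber) or one rich in fat and sugar (44% fat+fiber) at 6 weeks of age. Tissue was taken at 15 weeks. Libraries were made from 100 ng of RNA each with oligo-dT selection, and were read as 100 bp pairs toward a target of 30 M read pairs (M, mega), per the labels' protocols. Each of 47 libraries was mapped to 1 of 12 groups of strain, sex and diet. Groups held 4 libraries, except CAST/EiJ males on 10% fat with 3. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between samples. Replicate numbers follow the order of the deposited samples and carry no pairing.

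The submitters' processing notes name the genome build GRCm38 and DESeq2, without versions. Aligner, quantifier, annotation release and any use of strain-specific genomes are not given in the sources used here. The authors deposited a table of expected counts (estimated counts per gene and library, not scaled) for 20796 genes, of which 81.19% of the values were whole to within 1e-06. The other values were fractional, the form given by estimators that share a read among several genes. The authors also deposited variance-stabilized values on a log2 scale and a gene table with positions. Each deposited gene was above 0 in at least 24 libraries, so genes seen in fewer libraries had already been removed. A gene that only 1 strain expresses could be missing for that reason. Identifiers matched GENCODE M21 for 20677 genes, the chromosome was equal for 100% of these, and the start for 85.94%. Positions are those of the deposited gene table on GRCm38, as whole-gene spans. Total expected counts ranged from 26.04 M to 84.79 M per library, with a median of 40.79 M. For technical copies a ratio of chi-squared to degrees of freedom near 1 would hold. Between replicates of a group it ranged from 13.92 to 144.8 over 69 pairs, so over all genes together the spread between samples exceeded counting error.

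Expected counts were rounded to whole numbers before every fit. Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 12 groups, which left 17159 genes. Libraries were scaled by TMM factors, and a quasi-likelihood negative binomial model with 12 group terms and the identifier run was fitted to all 47 libraries, with 33 residual degrees of freedom and a common dispersion of 0.0425. The identifier run splits the sample numbers in the titles into 3 stretches of consecutive numbers. Whether these runs are processing batches is not given in the labels. In NZO/HlLtJ, only the first run held both diets within each sex. Diet effects (44% against 10% fat) were tested in each strain as the mean over both sexes, and in each strain and sex. Strain differences were tested between libraries on 10% fat, as the mean over both sexes. Sex differences (female against male) were tested in each strain as the mean over both diets. Differences between these effects were tested with quasi-likelihood F tests. The threshold was an adjusted p of 0.05 (Benjamini-Hochberg over all genes tested), and every adjusted p of a gene is from edgeR unless another tool is named. An error after ± beside a log2 fold change is the standard error (SE) of the coefficient. It was obtained by dividing the coefficient by the square root of its F statistic. CPM were computed with the cpm function of edgeR and TMM factors. Given for a strain, sex or diet, CPM are the mean of the means of its groups.

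Gene lists for 37 pathways and cell types were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternative settings listed first below. Lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, which compares a list with all other genes. A preset correlation of 0.01 was used, with an adjustment over the lists within a comparison. The same test with a correlation estimated from the data stands beside it. Scores of a list are the mean log2 CPM of its members in a library. Genes were named by a rule. Among called protein-coding genes with a regular symbol, a mean of 5 CPM on the higher side and the same sign in both sexes (or diets), those with the largest fold changes were taken, 8 in each direction for diet and strain comparisons and 5 for the others. For interactions, it took the 10 with the largest range of effects. Up to 4 members of each list with the smallest p were added, called or not, as were the Y-linked genes and Xist as a check of the sex labels. Of these, the genes in the lists described are printed. Exceptions chosen after their values were seen were Dnm3, Ttc25, Marc1, Sorcs2, AA914427 and Mrpl23-ps1 in the diet comparisons, Acot1, Acot2 and Fabp3 in NZO/HlLtJ males, Col6a1 and Col3a1 in NZO/HlLtJ, Amd1 in the strain comparison, and the genes compared over libraries in the closing part.

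Libraries in the direction of a difference are those that lay on its side of the mean of the compared libraries of the same sex (diet and strain comparisons) or the same diet (sex comparisons). A fold against a group with 0 counts was taken as a lower bound, against a floor of 3 counts over all libraries of that group. Bounds cover counting error only. Genes with another annotated gene in the table at 95% identity or more over a share of at least 0.5 of the shorter transcript (blastn 2.17.0) are named as copies, and their values are uncertain because reads could be given to either.

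The alternative settings fixed in advance were RLE size factors, no low-count filter, a stricter filter of 1 CPM in 20 libraries, DESeq2 1.42.0, limma on the deposited variance-stabilized values, no identifier run, a fit to the compared libraries alone, and each library left out in turn. After the data had been examined, 4 settings were added, namely the lymphocyte-marker score, that score with the adipocyte-marker score, the brown-adipocyte score (mean log2 CPM of Ucp1, Cidea, Elovl3, Otop1 and Kcnk3) in the model, and a fit without libraries of high lymphocyte score. That last fit was not run for comparisons that involve CAST/EiJ, where 3 libraries would remain. The fits with the lymphocyte and adipocyte scores had been looked at before they were listed as alternatives. Power was tested on counts simulated with the fitted dispersions and 200 changed genes of at least 1 CPM per comparison. At log2 fold changes of 0.5, 1 and 2, diet comparisons found 67.2% to 73.1%, 92.5% to 95.5% and 98.5% to 100% of these over strains. Sex comparisons found 62.7% to 73.1%, 91% to 95.5% and 97% to 100%. False calls numbered 4 to 13. Fitted dispersions omit a component shared by real libraries (34.4% of within-group variance), so real rates can differ. Power can be lower with fewer changed genes.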

Results

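Expression of 20796 genes was measured in gastrocnemius muscle from 47 mouse samples that fell into 12 groups of strain (C57BL/6J, CAST/EiJ or NZO/HlLtJ), sex and dietary fat (10% or 44%). Each group held 4 libraries, except CAST/EiJ males on 10% fat, which held 3. Total expected counts per library lay between 26.04 M and 84.79 M (M, mega), and 17159 genes were abundant enough to be tested. As a check of the sex labels, the 4 Y-linked genes were lower and 5 genes that escape X inactivation were higher in females in each strain. The series title gives the question as how strain and diet act together on susceptibility to type 2 diabetes. The comparisons were therefore diet within strain, strain within the control diet, sex within strain, and the differences between these effects.

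Lymphocyte transcripts set some libraries apart within groups. The mean log2 CPM of 12 lymphocyte markers lay at 0.977 or above in 23 libraries and at −2.61 or below in the other 24, with none between. The high libraries were 10 of 16 in C57BL/6J, 12 of 15 in CAST/EiJ and 1 of 16 in NZO/HlLtJ, and 8 of the 12 groups held libraries on both sides. Cd79a of the B-cell receptor ranged from 0 to 39.5 CPM, and Cd74, which chaperones class II antigen-presenting molecules, from 3.87 to 308 CPM. Ucp1, the heat-producing uncoupling protein of brown fat (chromosome 8, 83290348 to 83298456), exceeded 5 CPM in 15 libraries. Its group of 5 brown-adipocyte markers had mean log2 CPM of 3.07 in CAST/EiJ females and 3.35 in males on 10% fat, and 1.54 and 1.85 on 44% fat. In NZO/HlLtJ the same means were 0.411 and −0.445 on 10% fat, and −1.07 and −1.33 on 44% fat. In C57BL/6J they lay between −2.1 and −1.71.

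**Figure D1:**
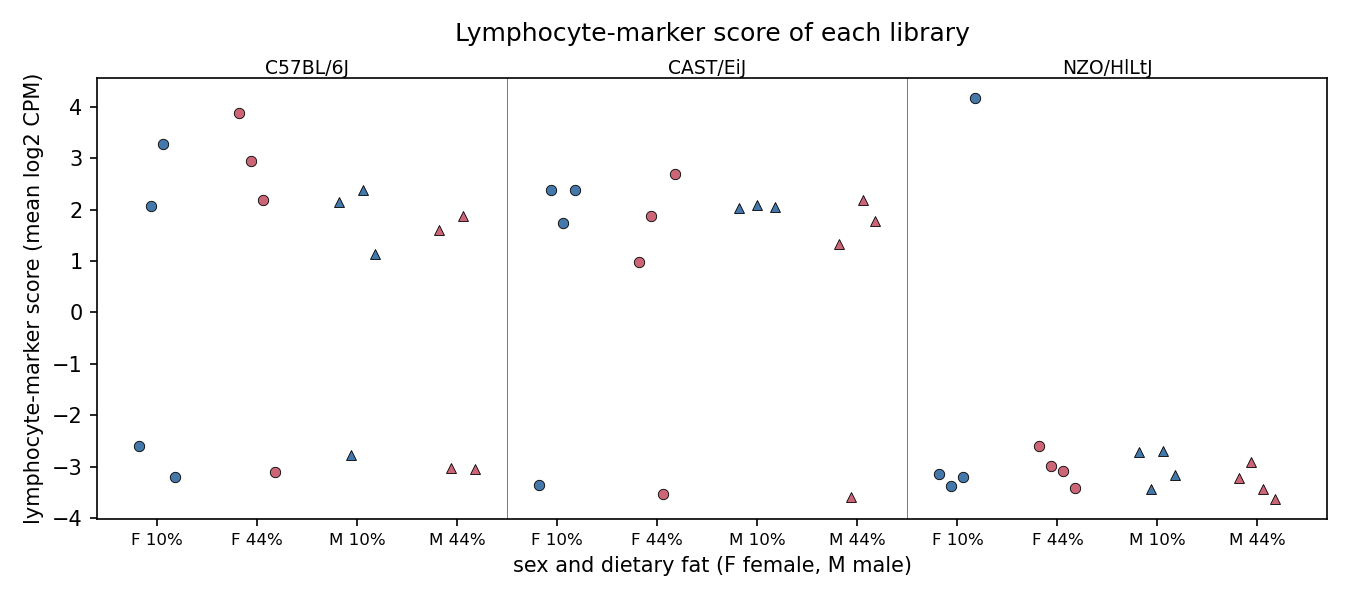
Lymphocyte-marker score (mean log2 CPM of 12 markers, vertical axis) of each of the 47 libraries by group (horizontal axis); each point is a library, circles are females, triangles are males, blue is 10% fat and red is 44% fat. No library lies between −2.61 and 0.977, and 1 of 16 NZO/HlLtJ libraries lies above that gap.

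In CAST/EiJ muscle, enzymes that make fatty acids fell on the 44% fat diet. Elovl6 (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495), which elongates long-chain fatty acids, fell from 27.6 to 3.12 CPM (log2 fold change −3.18 ± 0.51, SE, n = 7 and 8 libraries, adjusted p = 0.00068). Acly (ENSMUSG00000020917, chromosome 11, 100476353 to 100528000), which makes acetyl-CoA from citrate, fell from 305 to 45.1 CPM (−2.78 ± 0.43, adjusted p = 0.000471). Acaca, the enzyme that makes malonyl-CoA, fell from 323 to 84 CPM (−2.01 ± 0.35, adjusted p = 0.00288). Thrsp (chromosome 7, 97412938 to 97417730), a nuclear promoter of lipogenesis, fell from 167 to 46.7 CPM (−1.89 ± 0.42, adjusted p = 0.0476). The citrate carrier Slc25a1 (−2.10 ± 0.41, adjusted p = 0.0131) and the pentose phosphate enzyme Tkt (−2.10 ± 0.37, adjusted p = 0.0033) fell too. The glycogen phosphorylase Pygl fell as well (−2.06 ± 0.38, adjusted p = 0.00601). Each of these genes was lower in 8 of 8 libraries on 44% fat than the mean of the same sex on 10% fat. Across the transcriptome 23 genes passed, 1 higher and 22 lower, 18 of them changed at least 2-fold, and 825 had an unadjusted p under 0.05. The smallest p belonged to Ttc25 (chromosome 11, 100545607 to 100572568), a cilium gene beside Acly, at 0.329 against 2.99 CPM (−3.15 ± 0.34, adjusted p = 4.65e-07). The molybdenum enzyme Marc1 (chromosome 1, 184786767 to 184811313) fell by 3.76 ± 0.53 (adjusted p = 0.000105) and the sorting receptor Sorcs2 (chromosome 5, 36017180 to 36398139) fell by 1.19 ± 0.17 on the log2 scale (adjusted p = 0.000105). The single higher gene, the pseudogene Mrpl23-ps1, had 0.132 CPM against 0 and was above in 4 of 8 libraries.

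Of 15 measured genes of de novo lipogenesis, 5 fell, 0 rose and 10 did not pass in CAST/EiJ, and 11 fell when adjusted over the list alone. All 15 had a negative change, with a median log2 fold change of −0.64 (camera adjusted p = 1.07e-26, adjusted p = 0.00688 with an estimated correlation). The fifth called member was Acss2, which makes acetyl-CoA from acetate (−0.72 ± 0.15, adjusted p = 0.0193, 8 of 8 libraries). Within the 3 identifier runs, the mean lipogenesis score differed by −1, −0.938 and −0.864 between diets. The brown-adipocyte score moved with it, by −1.2, −1.9 and −0.974 in the same runs. Of 19 cholesterol synthesis genes, 0 passed and 10 fell when adjusted over the list alone (median −0.267, camera adjusted p = 1.34e-12, adjusted p = 0.134 with an estimated correlation). Among them the squalene epoxidase Sqle had −0.95 ± 0.28 (adjusted p = 0.376), Nsdhl −0.54 and Dhcr7 −0.38. Their score differed by −0.3, −0.204 and −0.214 within the runs. Of 19 fatty acid oxidation genes 0 passed, also when adjusted over the list alone, and 18 changes were positive (median 0.0733, camera adjusted p = 0.00249, adjusted p = 0.908 with an estimated correlation). Their score differed by 0.0737, or 0.031 without female 10% fat replicate 4 and 0.0435 without male 44% fat replicate 2. Of 20 genes of the fat-load response driven by PPAR receptors 0 passed, also when adjusted over the list alone, and 18 were positive (median 0.138, camera adjusted p = 0.000913, adjusted p = 0.819 with an estimated correlation). With the brown-adipocyte score in the model, chosen after the data were seen, Slc25a1, Thrsp and Acss2 lost their calls (adjusted p 0.0847, 0.236 and 0.189) while Elovl6, Acly and Acaca kept theirs. In that fit 36 genes passed, of which 21 were higher and 14 were among the 23. Over all alternatives, adjusted p ranged from 8.14e-11 to 0.0847 for Slc25a1, from 8.3e-06 to 0.236 for Thrsp and from 0.000213 to 0.399 for Acss2. Without CAST/EiJ male 10% fat replicate 2, the weakest of these fits for most genes, Thrsp had an adjusted p of 0.191, Slc25a1 of 0.0659 and Pygl of 0.0524 (range for Pygl 1.3e-11 to 0.0524). Thrsp lost its call without any of 11 of the 15 libraries, Acss2 without any of 7 and Slc25a1 without any of 4. The count of 23 was 36 without female 10% fat replicate 1, 14 without female 44% fat replicate 1, 13 without male 10% fat replicate 1, 11 without male 10% fat replicate 2 and 13 without female 10% fat replicate 3.

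**Figure D2:**
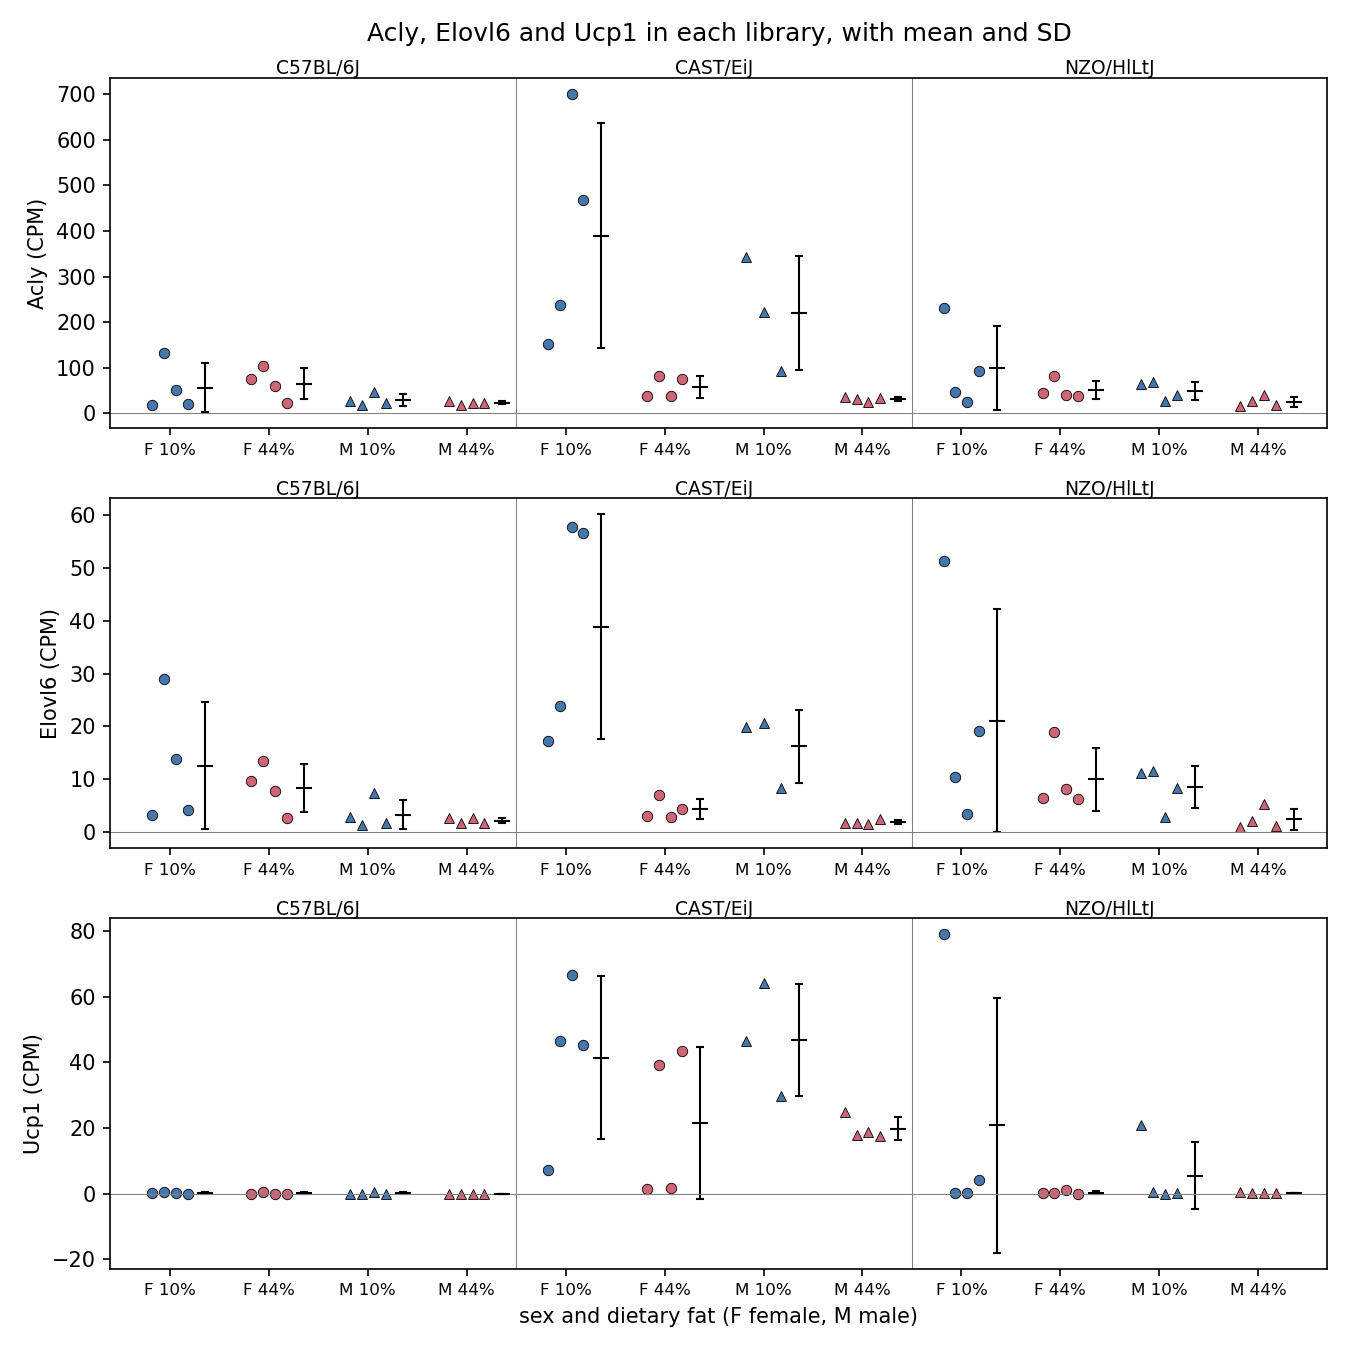
Expression in CPM (vertical axes) of Acly, Elovl6 and Ucp1 in each of the 47 libraries by group (horizontal axes); points are libraries, circles females, triangles males, blue 10% and red 44% fat, and black bars are the group mean with its SD. Acly lies between 93.7 and 700 CPM in the CAST/EiJ libraries on 10% fat and between 26.2 and 81.9 CPM in those on 44% fat.

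In NZO/HlLtJ muscle, 42 genes rose and 28 fell on the 44% fat diet, with a median absolute log2 fold change of 0.359, and 2224 genes had an unadjusted p under 0.05. Fabp3 (chromosome 4, 130308595 to 130315463), the fatty acid carrier of muscle (copy Fabp3-ps1), rose from 237 to 407 CPM (0.77 ± 0.17, SE, n = 8 and 8 libraries, adjusted p = 0.026). Acadl (chromosome 1, 66830839 to 66863277), a dehydrogenase of long-chain acyl-CoA, rose from 187 to 275 CPM (0.53 ± 0.11, adjusted p = 0.022). Ech1 (chromosome 7, 28825217 to 28832247), an isomerase of unsaturated fatty acids, rose from 115 to 162 CPM (0.49 ± 0.09, adjusted p = 0.00862). The GTPase Rab15 (chromosome 12, 76797960 to 76822908) rose from 5.11 to 10.3 CPM (1.04 ± 0.20, adjusted p = 0.00879). The other risers with large changes were Mss51, a muscle-enriched protein that restrains oxidative metabolism (0.88 ± 0.18, adjusted p = 0.0168), and Igfn1 (0.76 ± 0.17, adjusted p = 0.0298). Further risers were the amino acid transporter Slc38a2 (0.59 ± 0.13, adjusted p = 0.0353) and Phlda3, an inhibitor of Akt (0.46 ± 0.08, adjusted p = 0.00862). All of these were higher in 8 of 8 libraries. Ucp1 fell from 13.1 to 0.29 CPM (−5.11 ± 1.17, adjusted p = 0.0353). Its mean on 10% fat rested on 3 libraries with 79, 20.8 and 4.03 CPM, while the other 5 lay at 0.0297 to 0.646 CPM, within the range seen on 44% fat. Among the genes that fell were also Cyp2e1 (−1.61 ± 0.36, adjusted p = 0.032) and pyruvate carboxylase Pcx (−0.60 ± 0.15, adjusted p = 0.0499). The others were the syntrophin Sntb1 (−0.71 ± 0.17, adjusted p = 0.0392, 7 of 8 libraries), the replication helicase subunit Mcm2 (−0.52 ± 0.12, adjusted p = 0.0353) and Mtap of methionine salvage (−0.48 ± 0.09, adjusted p = 0.00879). The histone gene Hist1h2be (−0.48 ± 0.11, adjusted p = 0.0282) and Stbd1, which tethers glycogen (−0.47 ± 0.09, adjusted p = 0.015), fell as well. Apart from Ucp1 and Sntb1, all of these were lower in 8 of 8 libraries.

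Of 19 genes of mitochondrial fatty acid oxidation, 2 rose, 0 fell and 17 did not pass in NZO/HlLtJ, while 16 rose when adjusted over the list alone (median 0.229, camera adjusted p = 2.61e-17, adjusted p = 0.455 with an estimated correlation). Members short of the threshold included the carnitine carrier Slc25a20 (0.28, adjusted p = 0.0912), Cpt1b (0.23, adjusted p = 0.132), Acadvl (0.30, adjusted p = 0.0694) and Hadha (0.26, adjusted p = 0.0737). Of the 20 PPAR-driven genes, 2 rose, 0 fell and 18 did not pass, and 7 rose when adjusted over the list alone (median 0.237, camera adjusted p = 1.1e-07, adjusted p = 0.455 with an estimated correlation). Of 19 genes that break down branched-chain amino acids, 2 fell, 0 rose and 17 did not pass, with 10 lower and 1 higher when adjusted over the list alone (median −0.123, camera adjusted p = 1.45e-04, adjusted p = 0.625 with an estimated correlation). The leucine pathway enzymes Ivd (chromosome 2, 118861954 to 118882909; −0.29 ± 0.06, adjusted p = 0.015) and Mccc1 (−0.32 ± 0.06, adjusted p = 0.00879) fell in 8 of 8 libraries, while Ppm1k had −0.31 (adjusted p = 0.0737) and Bckdhb −0.23 (adjusted p = 0.0912). None of 15 lipogenesis genes passed, with 6 lower and 1 higher when adjusted over the list alone (median −0.316, camera adjusted p = 0.00592, adjusted p = 0.625 with an estimated correlation). Thrsp had −1.45 ± 0.43 (adjusted p = 0.113) and Elovl6 −1.42 ± 0.48 (adjusted p = 0.18). Of 10 adipocyte markers 0 passed and 1 was lower when adjusted over the list alone, with a median of −0.438 (camera adjusted p = 0.00402, adjusted p = 0.625 with an estimated correlation). In the single run that held both diets in each sex, the score differences were 0.189 for fatty acid oxidation, 0.232 for the PPAR list, −0.201 for branched-chain amino acids, −0.733 for lipogenesis, −0.739 for adipocyte markers and −1.99 for brown-adipocyte markers. None of 35 nuclear genes of oxidative phosphorylation passed, also when adjusted over the list alone, and 34 changes were positive (median 0.0623, camera adjusted p = 1.09e-04, adjusted p = 0.654 with an estimated correlation). Their score differed by 0.0628, or 0.0273 and 0.0411 without female 10% or 44% fat replicate 4. That of adipocyte markers differed by −0.517, or −0.319 without male 10% fat replicate 1.

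Of 18 named diet genes called in NZO/HlLtJ, 13 lost their call without some library. Rab15, Ech1, Phlda3, Mtap and Mccc1 kept theirs. Ucp1 had an adjusted p of 0.435 without male 10% fat replicate 1 (range over all alternatives 0.00146 to 0.715). Fabp3 had 0.104 without male 44% fat replicate 4 (range 0.00274 to 0.132), and Acadl 0.0772 without male 44% fat replicate 1 (range 0.000899 to 0.253). The count of 70 fell to 19 without male 44% fat replicate 4, 24 without male 44% fat replicate 1, 28 without female 44% fat replicate 4, 31 without female 10% fat replicate 4, 32 without male 10% fat replicate 1, 40 without female 10% fat replicate 1, and 46 without female 44% fat replicate 3 or male 10% fat replicate 3. It rose to 112 without male 44% fat replicate 2, 157 without female 10% fat replicate 2 and 195 without male 44% fat replicate 3. A fit to NZO/HlLtJ libraries alone called 3 genes, and DESeq2 called 228. With the brown-adipocyte score in the model 25 were called, 22 of them among the 70.

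In C57BL/6J muscle, no gene passed by edgeR (0 of 17159, 681 with an unadjusted p under 0.05, smallest adjusted p 0.0525), while DESeq2 called 12 and limma 3. The gene with the smallest p was Dnm3, a dynamin (−0.53 ± 0.10, SE, n = 8 and 8 libraries, adjusted p = 0.0525, lower in 8 of 8). The carnitine palmitoyltransferase Cpt2 had 52.8 against 43.2 CPM (0.29 ± 0.06, adjusted p = 0.0676) and Grb14, an adaptor that restrains the insulin receptor, 16.6 against 11.4 CPM (0.55 ± 0.11, adjusted p = 0.0676), each higher in 8 of 8. Ech1 had 0.37 ± 0.09 (adjusted p = 0.205), Acaa2 0.31 ± 0.08 (adjusted p = 0.491), Decr1 0.25 ± 0.07 (adjusted p = 0.498) and Fabp3 0.60 ± 0.17 (adjusted p = 0.498), all higher in 8 of 8. Of 19 fatty acid oxidation genes, 0 passed over all genes and 10 rose when adjusted over the list alone. Of these 19, 18 had a positive change (median 0.188, camera adjusted p = 9.84e-20, adjusted p = 0.324 with an estimated correlation), and the score differed by 0.055, 0.23 and 0.248 within the runs. Of 20 PPAR-driven genes, 0 passed, 3 rose when adjusted over the list alone and 16 were positive (median 0.125, or 0.0264 without genes shared with other lists, camera adjusted p = 1.62e-06, adjusted p = 0.608 with an estimated correlation). Among 18 genes of glycolysis and glycogen 0 passed, also when adjusted over the list alone, and 15 were negative (median −0.0687, camera adjusted p = 3.14e-04, adjusted p = 0.867 with an estimated correlation). Lipogenesis genes had a median of −0.00784 (camera adjusted p = 0.695), and 0 of 15 passed. The count of 0 became 1 without any of female 44% fat replicates 2 and 4, female 10% fat replicates 2 and 3, male 44% fat replicate 2 and male 10% fat replicate 4.

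**Figure D3:**
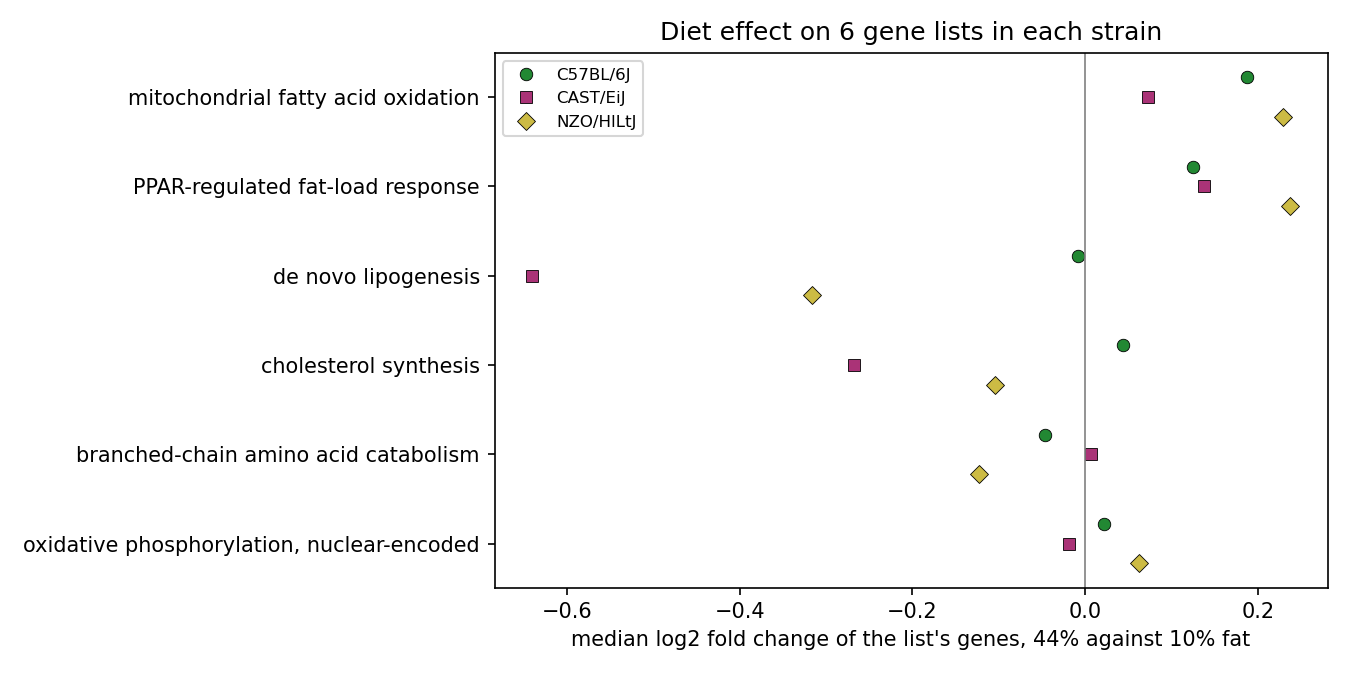
Median log2 fold change (44% against 10% fat, horizontal axis) of 6 gene lists in each strain (colours); points are medians over the measured genes of a list. Lipogenesis lies at −0.64 in CAST/EiJ, −0.316 in NZO/HlLtJ and −0.00784 in C57BL/6J, while fatty acid oxidation lies at 0.0733, 0.229 and 0.188.

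Within single sexes fewer genes passed. In CAST/EiJ females 3 genes fell (801 with an unadjusted p under 0.05), namely Ttc25 (−3.07 ± 0.47, adjusted p = 0.00169), AA914427 (−3.24 ± 0.51, adjusted p = 0.00169) and Sorcs2 (−1.29 ± 0.23, adjusted p = 0.0131), each in 4 of 4 libraries. In CAST/EiJ males Ttc25 alone fell (−3.24 ± 0.48, n = 3 and 4 libraries, adjusted p = 0.00131; 764 with an unadjusted p under 0.05). In C57BL/6J females the Hippo pathway gene Sav1 (chromosome 12, 69965012 to 69987002) fell from 66.7 to 48.8 CPM (−0.45 ± 0.08, adjusted p = 0.0308). In C57BL/6J males edgeR and limma called 0 genes, DESeq2 called 0, and 536 had an unadjusted p under 0.05. In NZO/HlLtJ males 7 genes rose and 3 fell. Ech1 (0.74 ± 0.13, adjusted p = 0.0105), Acadl (0.82 ± 0.16, adjusted p = 0.0348), the acyl-CoA thioesterase Acot1 (chromosome 12, 84009502 to 84017670; 2.57 ± 0.48, adjusted p = 0.0166), Rab15 (1.46 ± 0.29, adjusted p = 0.0348), the coenzyme A carrier Slc25a42 (0.59 ± 0.12, adjusted p = 0.0348) and the gluconeogenic enzyme Fbp2 (1.08 ± 0.23, adjusted p = 0.0472, 3 of 4 libraries) rose. Ivd (−0.51 ± 0.09, adjusted p = 0.0105), Mccc1 (−0.50 ± 0.09, adjusted p = 0.0105) and the secreted Wnt antagonist Frzb (−0.82 ± 0.17, adjusted p = 0.0458) fell. All but Fbp2 did so in 4 of 4 libraries.

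In these NZO/HlLtJ males 13 of 19 fatty acid oxidation genes and 13 of 20 PPAR-driven genes rose when adjusted over the list alone, and 2 of each over all genes. The medians were 0.324 (camera adjusted p = 1.19e-17, adjusted p = 0.273 with an estimated correlation) and 0.614 (camera adjusted p = 1.81e-14, adjusted p = 0.16 with an estimated correlation). Of 19 branched-chain amino acid genes 2 fell, 0 rose and 17 did not pass, with 10 lower when adjusted over the list alone (median −0.188, camera adjusted p = 1.76e-08, adjusted p = 0.273 with an estimated correlation). In NZO/HlLtJ females none of these 19 and 20 genes passed, also when adjusted over the list alone. The median was 0.141 for fatty acid oxidation, with 18 positive (camera adjusted p = 3.98e-05, adjusted p = 0.944 with an estimated correlation). Its score differed by 0.152, or 0.0449 and 0.228 without 10% fat replicate 4 or 3. For the PPAR list the median was 0.032 with 11 of 20 positive, but the mean of −0.134 and the test (camera adjusted p = 0.714) pointed down. There 5 genes rose, Vwa7 (chromosome 17, 35016579 to 35026741; 0.69 ± 0.13, adjusted p = 0.0224), Rab40b (0.52 ± 0.10, adjusted p = 0.0338), the proteasome-gene activator Nfe2l1 (0.47 ± 0.09, adjusted p = 0.0338), Nacc2 (0.44 ± 0.08, adjusted p = 0.0224) and the amyloid precursor App (0.32 ± 0.06, adjusted p = 0.0338). Cyfip2 (−2.33 ± 0.43, adjusted p = 0.0224) and the potassium channel subunit Kcnab1 (−1.01 ± 0.20, adjusted p = 0.0338) fell, and each of the 7 moved in 4 of 4 libraries. The lymphocyte markers moved beside them, with 0 of 12 passed over all genes, 12 lower when adjusted over the list alone and a median of −5.78 (camera adjusted p = 0.0555), since 1 of 4 libraries on 10% fat and none on 44% fat lay above the gap.

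Each of the 7 calls in NZO/HlLtJ females was lost without some library. The count was 0 without 10% fat replicate 4 or 44% fat replicate 4, 1 without 10% fat replicate 1 or 3, 3 without 44% fat replicate 2 or 3, and 22 without 10% fat replicate 2. In NZO/HlLtJ males the 10 calls became 0 without 44% fat replicate 1 or 4, 3 without 10% fat replicate 1 or 2, 4 without 10% fat replicate 4, 5 without 10% fat replicate 3, 49 without 44% fat replicate 2 and 88 without 44% fat replicate 3. In C57BL/6J females the count of 1 became 0 without 10% fat replicate 1 or 4 or 44% fat replicate 1 or 3, 5 without 10% fat replicate 2, and 7 without 10% fat replicate 3 or 44% fat replicate 4. In CAST/EiJ females the 3 calls became 16 without 10% fat replicate 1, 5 without 10% fat replicate 2 and 6 without 10% fat replicate 4, and in males the count of 1 became 2 without 10% fat replicate 3. Sorcs2 had an adjusted p of 0.124 without female 10% fat replicate 3 (range over all alternatives 0.000112 to 0.608).

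The diet effect differed between strains for 2 genes (1063 with an unadjusted p under 0.05). For Ttc25 (F test adjusted p = 0.00268) the log2 fold change was −0.25 in C57BL/6J, −3.15 in CAST/EiJ and −0.36 in NZO/HlLtJ, and for Marc1 (adjusted p = 0.00889) it was 0.22, −3.76 and 0.12. The effect in CAST/EiJ minus that in C57BL/6J was −2.90 ± 0.48 for Ttc25 (adjusted p = 0.00795) and −3.99 ± 0.70 for Marc1 (adjusted p = 0.0143). With limma the F test of Marc1 had an adjusted p of 0.0659. None of the 15 lipogenesis genes passed this F test and 7 did when adjusted over the list alone. Their median difference between diet effects was −0.862 for CAST/EiJ minus C57BL/6J (camera adjusted p = 4.44e-17, adjusted p = 0.0729 with an estimated correlation), with 9 lower when adjusted over the list alone. It was 0.324 for NZO/HlLtJ minus CAST/EiJ (camera adjusted p = 1.32e-06, adjusted p = 0.651 with an estimated correlation), with 5 higher when adjusted over the list alone, and −0.401 for NZO/HlLtJ minus C57BL/6J (camera adjusted p = 0.0115, adjusted p = 0.666 with an estimated correlation), with 0 passed when adjusted over the list alone. For fatty acid oxidation the median differences were −0.117 (camera adjusted p = 0.00101, adjusted p = 0.799 with an estimated correlation), 0.172 (camera adjusted p = 1.32e-06, adjusted p = 0.651 with an estimated correlation) and 0.0413 (camera adjusted p = 0.114), with 0 passed over all genes or over the list alone. The second difference was 0.159 in scores, or 0.106 without NZO/HlLtJ female 10% fat replicate 4. No gene was called in both CAST/EiJ and NZO/HlLtJ, where chance alone gives 0.0359 shared lower and 0.00245 shared higher genes. Of the 70 genes called in NZO/HlLtJ, 55 had the same sign in C57BL/6J and 53 in CAST/EiJ. Of the 23 called in CAST/EiJ, 15 had the same sign in C57BL/6J and 19 in NZO/HlLtJ. The count of 2 was 4 without NZO/HlLtJ female 10% fat replicate 1 or 4.

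No gene passed the test of a diet effect that differs between the sexes (0 by edgeR and 0 by limma, 2 by DESeq2, 894 with an unadjusted p under 0.05, smallest adjusted p 0.708). The count was 1 without NZO/HlLtJ male 44% fat replicate 2 or C57BL/6J female 44% fat replicate 4.

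On the control diet, NZO/HlLtJ and C57BL/6J differed in 4432 genes, 2304 higher and 2128 lower in NZO/HlLtJ (6236 with an unadjusted p under 0.05), of which 1012 differed at least 2-fold. Slow-fibre genes were higher in NZO/HlLtJ, with 9 of 11 higher, 0 lower and 2 not passed, and 9 higher and 1 lower when adjusted over the list alone (median 1.11, camera adjusted p = 3.17e-07, adjusted p = 0.94 with an estimated correlation). Slow troponin Tnnt1 (chromosome 7, 4504570 to 4516382) differed by 1.54 ± 0.17 (SE, n = 8 and 8 libraries, adjusted p = 1.95e-09), slow troponin Tnni1 by 1.46 ± 0.18 and the myosin Myh7b had 9.16 against 3.38 CPM (adjusted p = 2.79e-08). Slc15a5 had 18.3 against 3.12 CPM (3.13 ± 0.28, adjusted p = 1.55e-11) and the glutathione transferase Gstm7 11 against 1.58 CPM (2.89 ± 0.14, adjusted p = 6.2e-19). Securin Pttg1 was lower, at 0.823 against 27.6 CPM (−5.07 ± 0.16, adjusted p = 5.52e-25), as were Rab6b (−4.55 ± 0.24) and Tceanc2 (−4.00 ± 0.10). Each of these differences had the same direction in 8 of 8 NZO/HlLtJ libraries. Ucp1 was higher in 6 of 8 (13.1 against 0.189 CPM, 5.38 ± 1.31, adjusted p = 0.00176), and its adjusted p was 0.0942 without NZO/HlLtJ male 10% fat replicate 1 (range over all alternatives 3.91e-06 to 0.457).

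Of 14 genes of the tricarboxylic acid cycle 10 were higher in NZO/HlLtJ, 0 lower and 4 not passed, with 13 higher and 1 lower when adjusted over the list alone (median 0.227, camera adjusted p = 1.24e-04, adjusted p = 0.94 with an estimated correlation), such as Idh3b (0.32 ± 0.05), Dld (0.34 ± 0.06) and Pdha1 (0.29 ± 0.06). Of 35 oxidative phosphorylation genes 19 were higher, 1 lower and 15 not passed, with 20 and 2 when adjusted over the list alone (median 0.157, camera adjusted p = 1.3e-04, adjusted p = 0.94 with an estimated correlation). Ndufb5 of complex I differed by 0.57 ± 0.07 (adjusted p = 1.89e-08) and Cox6a2 of complex IV by −0.41 ± 0.07 (adjusted p = 7.08e-06). Of 18 interferon-response genes 1 was higher, 11 lower and 6 not passed, with 1 and 12 when adjusted over the list alone (median −0.59, camera adjusted p = 4.5e-04, adjusted p = 0.94 with an estimated correlation). Ifit3 differed by −1.46 ± 0.24 (adjusted p = 1.07e-05) and Mx2 by −4.19 ± 0.50 (adjusted p = 3.61e-08), while Mx1 was higher (2.40 ± 0.47, adjusted p = 0.000121). Of 13 antigen presentation genes 5 were lower, 0 higher and 8 not passed, also when adjusted over the list alone (median −0.703, camera adjusted p = 0.0154, adjusted p = 0.94 with an estimated correlation). Lymphocyte markers moved with them, since 1 of 8 NZO/HlLtJ and 5 of 8 C57BL/6J libraries on 10% fat lay above the gap. The satellite-cell factor Pax7 was lower (−0.94 ± 0.17, adjusted p = 4.23e-05), as was the insulin-pathway kinase Akt2 (−0.29 ± 0.05, adjusted p = 5.64e-06), while Grb14 was higher (0.65 ± 0.12, adjusted p = 3.83e-05). Within runs the slow-fibre score differed by 1.05, 0.86 and 0.934, the oxidative phosphorylation score by 0.0468, 0.215 and 0.182, and the interferon score by −0.672, −0.517 and −0.603. Leaving out libraries above the lymphocyte gap, a choice made after the data were seen, gave 2397 genes in place of 4432.

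CAST/EiJ and C57BL/6J differed in 8526 genes, 4125 higher and 4401 lower in CAST/EiJ (9388 with an unadjusted p under 0.05), of which 2448 differed at least 2-fold. Slow-fibre genes were higher here too, 10 of 11, with 0 lower, 1 not passed and 10 higher when adjusted over the list alone (median 1.09, camera adjusted p = 0.00174, adjusted p = 0.974 with an estimated correlation). The slow myosin Myh7 (chromosome 14, 54970688 to 54994634) differed by 1.35 ± 0.19 (SE, n = 7 and 8 libraries, adjusted p = 1.33e-07, 6 of 7 libraries), Myh7b by 1.61 ± 0.19 (7 of 7), and Tnni1 had 93.2 against 34.4 CPM (adjusted p = 1.05e-08, 7 of 7). Lipid-making genes were higher on this diet, 11 of 15 over all genes with 0 lower and 4 not passed, and also 11 when adjusted over the list alone (median 0.79, camera adjusted p = 0.00174, adjusted p = 0.974 with an estimated correlation). Among them were Thrsp at 2.91 ± 0.43 (adjusted p = 4.98e-07), Acly at 2.86 ± 0.43 (adjusted p = 6.27e-07), Acaca at 2.12 ± 0.35 (adjusted p = 3.98e-06) and the desaturase Fads1 at 0.79 ± 0.12 (adjusted p = 5.05e-07), in 7 of 7 libraries each. Of 18 genes of lipid uptake, storage and lipolysis 14 were higher, 0 lower and 4 not passed, also when adjusted over the list alone (median 0.56, camera adjusted p = 0.00174, adjusted p = 0.974 with an estimated correlation). They included the lipase Pnpla2 (0.92 ± 0.11, adjusted p = 2.41e-09), the lipid-droplet coat Plin2 (1.23 ± 0.17, adjusted p = 1.8e-07), Abhd5 (0.43 ± 0.05) and Acsl1 (0.63 ± 0.10). The brown-adipocyte score was higher too, and Ucp1 had 44.1 against 0.189 CPM (7.88 ± 1.18, adjusted p = 6.04e-07, 7 of 7 libraries). With that score in the model, the lipogenesis median was −0.126, Acly had 0.127 (adjusted p = 0.865) and the calls of Thrsp, Fads1, Acaca, Plin2 and Acsl1 ended. On 10% fat that score parts these strains completely, so strain and brown fat are not separated by this fit. The adjusted p of Acly ranged from 4.75e-11 to 0.865 over the alternatives. Within runs the lipogenesis score differed by 1.43, 1.14 and 1.33, and the slow-fibre score by 1.2, 1.02 and 0.788.

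Interferon-response genes were mostly lower in CAST/EiJ, 13 of 18, with 3 higher and 2 not passed (median −1.14, camera adjusted p = 0.00174, adjusted p = 0.974 with an estimated correlation), the same counts as when adjusted over the list alone. They included Oasl2 (−2.73 ± 0.23, adjusted p = 8.62e-13), the transcription factor Irf7 (−2.67 ± 0.28, adjusted p = 3.64e-10), Ifit3 (−2.48 ± 0.27) and Rsad2 (−2.12 ± 0.22), in 7 of 7 libraries each, and the score differed by −1.13, −1.06 and −1.16 within runs. Of 10 endothelial markers 7 were lower, 0 higher and 3 not passed, also when adjusted over the list alone (median −0.262, camera adjusted p = 0.0493, adjusted p = 0.974 with an estimated correlation), such as Cdh5 (−0.58 ± 0.07) and Pecam1 (−0.42 ± 0.07). Of 35 oxidative phosphorylation genes 19 were higher, 1 lower and 15 not passed, or 24 and 2 when adjusted over the list alone (median 0.151, camera adjusted p = 0.00174, adjusted p = 0.974 with an estimated correlation). The polyamine enzyme Amd1 (chromosome 10, 40287458 to 40302188) was lower (−1.37 ± 0.13, adjusted p = 4.59e-11), but Amd2, its near-identical copy, had 288 against 4.25 CPM. Summed with Amd2 and a further copy, Amd-ps3, Amd1 had 669 CPM in CAST/EiJ, 773 in NZO/HlLtJ and 1160 in C57BL/6J. Among other large differences, the acetylcholine receptor subunit Chrna9 had 33.6 against 0.436 CPM (7.58 ± 0.38, adjusted p = 2.05e-19), Gad1, which makes the transmitter GABA, 10.6 against 0.0941 CPM (6.87 ± 0.53, adjusted p = 2.74e-13), and Tmem232 a log2 fold change of 6.86 ± 0.28. Fam213b (chromosome 4, 154895504 to 154899135) had 0 counts in CAST/EiJ against 55.2 CPM, at least 5480-fold lower, and the interferon-induced GTPase Iigp1 (chromosome 18, 60376029 to 60392627) 0 against 8.25 CPM, at least 819-fold lower. Efcab6 had 1 count in all CAST/EiJ libraries against 8.74 CPM.

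Several of the largest strain differences fell on genes with a near-identical copy, and their values are uncertain. mt-Co2, a mitochondrial subunit of complex IV (MT, 7013 to 7696), had 10.4 CPM in CAST/EiJ against 3300 in C57BL/6J. Summed with its copies Gm13341 and Gm28661 it had 8690 against 8730 CPM. Hist2h2aa2 (chromosome 3, 96239749 to 96240276) had 13.5 CPM in NZO/HlLtJ and 0 counts in C57BL/6J, at least 1385-fold higher, while its sum with copies was lower in NZO/HlLtJ, at 28.3 against 36.5 CPM. Hba-a1, a globin, had a log2 fold change of 7.67 in NZO/HlLtJ, and its sum with Hba-a2 was 283 against 271 CPM. The cardiac myosin Myh6 had 31.3 CPM in NZO/HlLtJ against 1.84 in C57BL/6J (4.07 ± 0.20, adjusted p = 8.84e-19), and its sum with the copy Myh7 was 1190 against 472 CPM. The antiviral Trim12a was lower there (−3.91 ± 0.29), and its sum with Trim12c and Trim5 was 10.9 against 14.7 CPM. Tpm3-rs7 (copy Tpm3), Eno1b (copies Eno1 and Gm4735), Gbp10 (Gbp11 and Gbp6), Mndal (Ifi203, Ifi204, Ifi205 and Mnda) and Tgtp2 (Gm12185 and Tgtp1) were other cases. The pancreatic amylases Amy2a2 and Amy2a3 were called lower in both other strains because of 1 library. C57BL/6J female 10% fat replicate 1 had 112 and 312 CPM, and no other library exceeded 0.321 and 1.07 CPM.

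NZO/HlLtJ and CAST/EiJ differed in 8576 genes, 4485 higher and 4091 lower in NZO/HlLtJ (9509 with an unadjusted p under 0.05), of which 2495 differed at least 2-fold. Fatty acid synthesis genes and some genes of amino acid breakdown were lower in NZO/HlLtJ. Of 15 lipogenesis genes 12 were lower, 0 higher and 3 not passed, also when adjusted over the list alone (median −0.836, camera adjusted p = 0.00485, adjusted p = 0.958 with an estimated correlation). They included Fads1 (−1.03 ± 0.12, SE, n = 8 and 7 libraries, adjusted p = 3.16e-09) and the malic enzyme Me1 (−0.75 ± 0.09, adjusted p = 1.04e-08). Their score differed by −0.67, −1.14 and −0.866 within runs. The brown-adipocyte score was lower in NZO/HlLtJ too, and with it in the model the median was −0.318 (camera adjusted p = 0.39), while Fads1 and Me1 kept their calls. Of 19 branched-chain amino acid genes 10 were lower, 5 higher and 4 not passed, also when adjusted over the list alone (median −0.209, camera adjusted p = 0.105). Bckdhb (−0.87 ± 0.07, adjusted p = 8.39e-14), Mut (−0.71 ± 0.05, adjusted p = 1.01e-14) and Auh (−0.49 ± 0.04, adjusted p = 8.38e-12) were lower as well. Irf7 (2.01 ± 0.28, adjusted p = 1.55e-07) and Oasl2 (1.95 ± 0.23, adjusted p = 2.85e-09) were higher. Fam213b had 65.5 CPM against 0 counts, at least 6502-fold higher. Tmem45b was higher (8.41 ± 0.96), and Gad1 (−7.17 ± 0.55) and Chrna9 (−6.44 ± 0.33) were lower. Every named difference had its direction in 8 of 8 NZO/HlLtJ libraries.

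Between the sexes, polyamine genes were lower in females in each strain. Amd1, which makes the aminopropyl donor of polyamine synthesis, had 201 CPM in females and 2060 in males of C57BL/6J (−3.32 ± 0.14, SE, n = 8 and 8 libraries, adjusted p = 8.55e-21). It had 118 against 555 CPM in CAST/EiJ (−2.25 ± 0.13, n = 8 and 7, adjusted p = 1.33e-15) and 167 against 1410 CPM in NZO/HlLtJ (−3.07 ± 0.13, n = 8 and 8, adjusted p = 7.62e-20). Ornithine decarboxylase Odc1 (−1.76, −0.75 and −1.63 in the order of the strains above) and spermine oxidase Smox (−2.34, −1.87 and −2.03) were lower too, and all 3 genes were lower in 8 of 8 female libraries of each strain. Of 11 polyamine genes, 7 were lower, 1 higher and 3 not passed in C57BL/6J, 5 lower, 0 higher and 6 not passed in CAST/EiJ, and 6 lower, 0 higher and 5 not passed in NZO/HlLtJ. When adjusted over the list alone, 7 were lower and 1 higher in C57BL/6J and in NZO/HlLtJ, and 5 lower in CAST/EiJ. The medians were −0.212, −0.051 and −0.238 (camera adjusted p = 1.94e-09, 1.36e-09 and 4.75e-10). This list kept its call with an estimated correlation, with adjusted p of 4.17e-04, 3.35e-04 and 2.6e-04. The solute carrier Slc15a5 (chromosome 6, 137983586 to 138079916) was lower in females as well (−5.11 ± 0.32, −3.03 ± 0.23 and −3.48 ± 0.23), as was complement component C7 (−4.01 ± 0.21, −2.35 ± 0.22 and −2.96 ± 0.20). The zinc transporter Slc30a2 (chromosome 4, 134343181 to 134354484) differed by −3.93 ± 0.18 in C57BL/6J and −3.68 ± 0.17 in NZO/HlLtJ. The score differences of the polyamine list within runs were −0.915, −1.02 and −0.958 in C57BL/6J, −0.592, −0.756 and −0.611 in CAST/EiJ, and −0.799 in the single NZO/HlLtJ run with both sexes on the same diet.

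Slow-fibre genes were higher in females of C57BL/6J, 11 of 11 over all genes and also when adjusted over the list alone (median 0.786, camera adjusted p = 7.41e-11, adjusted p = 0.174 with an estimated correlation). They were higher in females of NZO/HlLtJ in the same numbers, 11 of 11 (median 0.744, camera adjusted p = 5.28e-12, adjusted p = 0.13 with an estimated correlation). In CAST/EiJ 0 of 11 passed, also when adjusted over the list alone, although all 11 were positive (median 0.213, camera adjusted p = 0.0589). Tnnt1 differed by 1.17 ± 0.17 in C57BL/6J (adjusted p = 1.68e-06) and 0.89 ± 0.16 in NZO/HlLtJ (adjusted p = 0.000142), Myh7 by 1.14 ± 0.18 and 0.94 ± 0.18, and Myl2 by 1.05 ± 0.15 and 0.94 ± 0.15, each higher in 8 of 8 female libraries. The slow-fibre score differed by 0.792, 0.815 and 1.11 within runs in C57BL/6J, 0.264, 0.585 and −0.205 in CAST/EiJ, and 0.902 in NZO/HlLtJ.

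**Figure D4:**
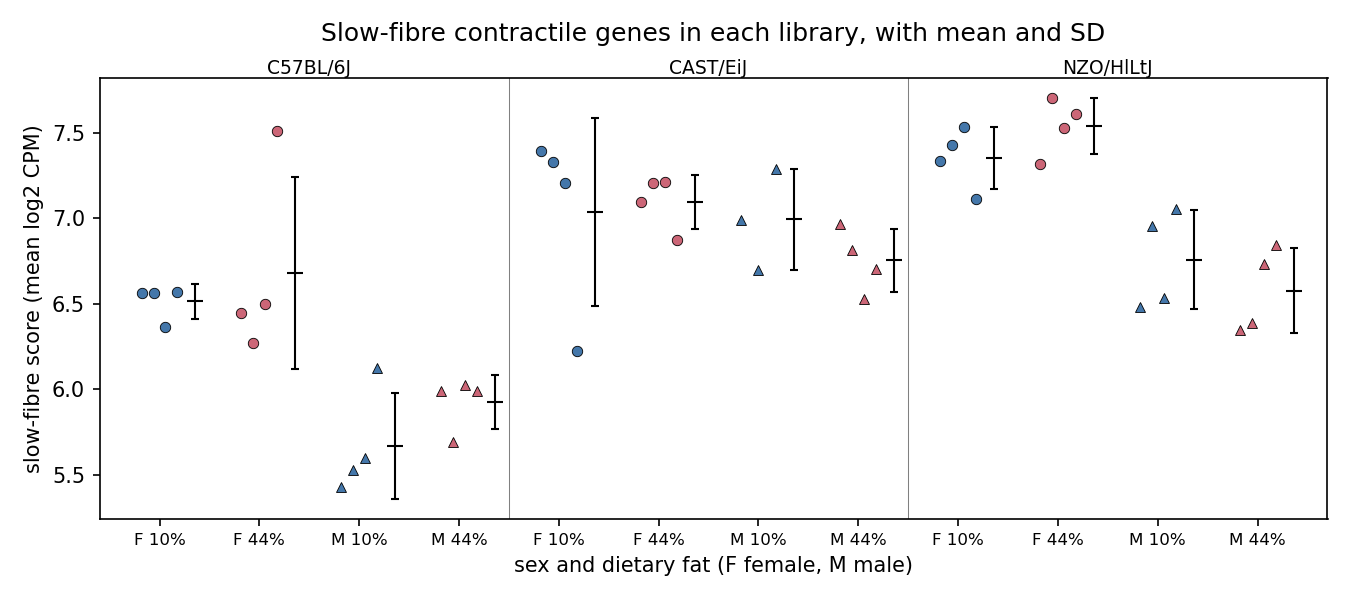
Slow-fibre score (mean log2 CPM of 11 genes, vertical axis) of each of the 47 libraries by group (horizontal axis); points are libraries, circles females, triangles males, blue 10% and red 44% fat, with black bars for the group mean and its SD. On 10% fat the means were 6.51 in females and 5.67 in males of C57BL/6J, and 7.35 and 6.76 in NZO/HlLtJ.

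In C57BL/6J 2606 genes differed between the sexes, 1116 higher and 1490 lower in females (4687 with an unadjusted p under 0.05). Without libraries above the lymphocyte gap, in a fit with fewer samples, the count was 423, with 151 higher. The prolactin receptor Prlr (chromosome 15, 10177238 to 10349180) had 7.07 against 0.459 CPM (3.98 ± 0.49, adjusted p = 9.16e-08) and the oxytocin receptor Oxtr a log2 fold change of 3.84 ± 0.85 (adjusted p = 0.00126). Mybph, a thick-filament protein, had 330 against 54.9 CPM (2.57 ± 0.18, adjusted p = 4.42e-14), and each was higher in 8 of 8 libraries. The actin-nucleating Actr3b (chromosome 5, 25759997 to 25850688) was lower (−3.72 ± 0.14, adjusted p = 1.14e-22). Of 18 circadian clock genes 6 were lower, 0 higher and 12 not passed, with 8 lower when adjusted over the list alone (median −0.149, camera adjusted p = 0.00219, adjusted p = 0.11 with an estimated correlation). Lower genes included Bhlhe41 (−1.15 ± 0.13), Hlf (8.64 against 17.1 CPM) and Per2 (−1.21 ± 0.29, adjusted p = 0.00338). Of 13 mitochondrial genome transcripts 8 were lower, 0 higher and 5 not passed, or 11 lower when adjusted over the list alone (median −0.338, camera adjusted p = 1.05e-05, adjusted p = 0.514 with an estimated correlation). Without libraries above the lymphocyte gap mt-Co1 had an adjusted p of 0.935, against 0.00481 over all libraries (−0.33 ± 0.08; range over all alternatives 0.000518 to 0.935). Of 9 Schwann cell markers 8 were higher, 0 lower and 1 not passed, or 9 higher when adjusted over the list alone (median 0.727, camera adjusted p = 1.05e-05, adjusted p = 0.229 with an estimated correlation), among them Mbp of myelin (0.86 ± 0.22). Of 18 interferon-response genes 3 were higher, 0 lower and 15 not passed, also when adjusted over the list alone. They included Oas1a (1.09 ± 0.30, adjusted p = 0.00841) and Oasl2 (0.73 ± 0.20, adjusted p = 0.00828), and the list median was 0.445 (camera adjusted p = 8.76e-04, adjusted p = 0.651 with an estimated correlation). Oasl2 had an adjusted p of 0.0725 without female 44% fat replicate 4 (range over all alternatives 0.000721 to 0.276). The score of adipocyte markers moved beside these, with 1 of 10 higher, 0 lower and 9 not passed, 4 higher when adjusted over the list alone and a median of 0.801 (camera adjusted p = 0.00304, adjusted p = 0.703 with an estimated correlation). The elastase Cela1 was called higher (2.83 ± 0.83, adjusted p = 0.0152) and had −0.05 without female 10% fat replicate 1, the library with pancreatic transcripts. Dmbt1, with 10.1 against 0.0653 CPM, was highest in that library too (25.9 CPM, next 19.4).

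In CAST/EiJ 732 genes differed between the sexes, 387 higher and 345 lower in females (2715 with an unadjusted p under 0.05), and the count was 448 without male 10% fat replicate 2. The keratin Krt18 (chromosome 15, 102028216 to 102032026) had 5.27 against 0.072 CPM (6.16 ± 0.81, adjusted p = 2.23e-06), Prlr a log2 fold change of 3.92 ± 0.49 (adjusted p = 8.58e-07) and the secreted glycoprotein Stc2 one of 2.22 ± 0.31 (adjusted p = 4.49e-06), higher in 8 of 8 libraries. Oxtr differed by 2.89 ± 0.70 (adjusted p = 0.0107) and had an adjusted p of 0.0524 without male 10% fat replicate 3 (range over all alternatives 0.000143 to 0.0524). Tmem266 was higher (1.68 ± 0.21) and B3gat1, an enzyme of the HNK-1 carbohydrate, lower (−2.56 ± 0.34). Of 18 clock genes 4 were higher, 3 lower and 11 not passed, with 7 and 5 when adjusted over the list alone (median 0.0249, camera adjusted p = 0.666). Per3 was higher (0.90 ± 0.16, adjusted p = 0.000292, 8 of 8 libraries). Of 35 oxidative phosphorylation genes 3 were lower, 0 higher and 32 not passed, also when adjusted over the list alone (median −0.0833, camera adjusted p = 8.87e-07, adjusted p = 0.909 with an estimated correlation). Their score differed by −0.101, or −0.0623 without female 10% fat replicate 4.

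In NZO/HlLtJ 2027 genes differed between the sexes, 894 higher and 1133 lower in females (4295 with an unadjusted p under 0.05). Cardiac actin Actc1 (2.12 ± 0.30, adjusted p = 2.21e-06), Cyfip2 (2.14 ± 0.31, adjusted p = 5.36e-06), Stc2 (1.77 ± 0.29, adjusted p = 3.4e-05) and Lrfn4 (1.59 ± 0.31, adjusted p = 0.000329) were higher in 8 of 8 female libraries. Of 20 insulin-signalling genes 5 were higher, 4 lower and 11 not passed, or 6 and 5 when adjusted over the list alone (median 0.038, camera adjusted p = 0.493). Tbc1d1, a regulator of glucose transporter traffic (1.10 ± 0.15, adjusted p = 2.43e-06), and Grb10 (0.62 ± 0.09, adjusted p = 3.29e-06) were higher, also in 8 of 8. Of 15 atrophy and autophagy genes 6 were lower, 0 higher and 9 not passed, also when adjusted over the list alone (median −0.285, or −0.0522 without genes shared with other lists, camera adjusted p = 0.00629, adjusted p = 0.547 with an estimated correlation). They included Eif4ebp1 (−0.68 ± 0.08, adjusted p = 2.11e-08) and the ubiquitin ligase gene Fbxo21 (−0.52 ± 0.09, adjusted p = 8.97e-05). Others were myostatin Mstn (−0.48 ± 0.11, adjusted p = 0.00279) and Ddit4, an inhibitor of mTORC1 (−2.65 ± 0.62, adjusted p = 0.00305, 7 of 8 libraries). The kinase Sgk1 was lower as well (−1.21 ± 0.23, adjusted p = 0.000292). Of 19 branched-chain amino acid genes 5 were higher, 0 lower and 14 not passed, or 6 higher when adjusted over the list alone (median 0.095, camera adjusted p = 0.00186, adjusted p = 0.567 with an estimated correlation), such as Dbt (0.61 ± 0.08). Of 18 clock genes 3 were lower and 15 not passed, or 4 lower when adjusted over the list alone (median −0.137, camera adjusted p = 0.00544, adjusted p = 0.13 with an estimated correlation), among them Bhlhe41 (−0.63 ± 0.13) and Hlf (−0.65 ± 0.15). Elovl6 was higher (1.68 ± 0.48, adjusted p = 0.0163, 7 of 8 libraries), with an adjusted p of 0.0831 without female 10% fat replicate 1 (range over all alternatives 0.00102 to 0.0867).

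The sex difference itself differed between strains for 563 genes (F test, 2630 with an unadjusted p under 0.05). Actr3b (adjusted p = 5.59e-13) and Slc30a2 (adjusted p = 5.06e-12) were lower in females by −3.72 and −3.93 in C57BL/6J, −0.88 and −0.98 in CAST/EiJ, and −1.96 and −3.68 in NZO/HlLtJ. The keratins Krt18 (adjusted p = 4.42e-06) and Krt8 (adjusted p = 8.08e-05), partners in simple epithelia, had differences of 3.08 and 4.26 in C57BL/6J and 6.16 and 7.06 in CAST/EiJ, against −1.92 and −1.5 in NZO/HlLtJ. Prlr (adjusted p = 0.00223) differed by 3.98, 3.92 and 0.72 in the same order. Of the 18 clock genes 8 passed this test and 14 did when adjusted over the list alone, among them Per3 (−0.05, 0.90 and −0.04, adjusted p = 0.00625) and Tef (−0.24, 0.23 and −0.18, adjusted p = 0.00297). Of 11 slow-fibre genes, Myl2 and Tnnt1 passed, or 8 when adjusted over the list alone. Of 11 polyamine genes Amd1, its near-identical copy Amd2 and Odc1 passed, or 4 when adjusted over the list alone. Oxtr (3.84, 2.89 and 0.03, adjusted p = 0.049) lost its call without any of 30 libraries. Its adjusted p was highest, 0.104, without NZO/HlLtJ male 10% fat replicate 1, and 0.173 with limma. Chrna9 (3.93, 0.55 and 1.64, adjusted p = 0.0126) had an adjusted p of 0.861 with limma.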

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

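The tests of a response shared by a group, of the adipocyte-marker and lymphocyte-marker scores in the CAST/EiJ model, the bound of the lymphocyte test, the node markers without Cr2 and Tnfsf11, the measure of mirrored copies, the copies searched or summed gene by gene, and all values of the brown-adipocyte score in gene fits were chosen after the results were seen. The other tests were fixed before their values were known, the brown-fat test after the levels of Ucp1 had been seen.

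Of 88 tests for a library that lies apart within its group, 9 found one, where chance gives about 1 in 20. NZO/HlLtJ female 44% fat replicate 2 had a total of 84.8 M counts (M, mega; others 39.9 M to 46.8 M) and 3.55% of counts from 18S ribosomal RNA (others 7.56% to 7.82%). C57BL/6J male 10% fat replicate 2 had 6.4% from 18S ribosomal RNA (others 9.04% to 9.55%). The slow-fibre score was low in C57BL/6J female 10% fat replicate 3 (6.36, others 6.56 to 6.57), C57BL/6J male 44% fat replicate 2 (5.69, others 5.99 to 6.03) and CAST/EiJ female 10% fat replicate 4 (6.22, others 7.21 to 7.39). The lymphocyte score was low in CAST/EiJ female 10% fat replicate 1 (−3.36, others 1.74 to 2.39) and CAST/EiJ male 44% fat replicate 2 (−3.6, others 1.33 to 2.19), and high in NZO/HlLtJ female 10% fat replicate 4 (4.17, others −3.38 to −3.13).

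The lymphocyte score parted libraries of the same strain, sex and diet. A response common to the mice of a group was argued against by 8 of 12 groups with libraries on both sides of the gap. Blood left in vessels was argued against by a median slope on the score of 0.0687 over platelet, neutrophil and red cell markers, with 0.064 for the abundant globin Hbb-bs, although the neutrophil genes S100a8 and S100a9 had 0.356 and 0.487. Lymph node tissue in some samples remains a candidate explanation, since 7 of 7 tested markers of node stroma and venules rose with the score (median slope 0.572), such as Cxcl13 at 0.0742 to 13.7 CPM and Ccl21a at 4.48 to 60.9 CPM. Without Cr2 and Tnfsf11, which lymphocytes also express, 5 of 5 rose (median 0.4). Adipocyte markers had a slope of 0.139, antigen presentation genes 0.295 and endothelial markers −0.0182, and the low share of NZO/HlLtJ libraries above the gap could reflect dissection or strain, which was not tested.

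Lipogenesis genes fell on 44% fat in CAST/EiJ, with a median of −0.558 on log2 CPM. The difference in diet effect was −0.862 for CAST/EiJ minus C57BL/6J and 0.324 for NZO/HlLtJ minus CAST/EiJ, and both lost their call with an estimated correlation (adjusted p = 0.0729 and 0.651). Fewer adipocytes in general were argued against as the whole cause. The median was −0.582 with the adipocyte-marker score in the model (camera adjusted p = 2.21e-40, adjusted p = 9.28e-05 with an estimated correlation). Abundant adipocyte transcripts had a median change of 0.139. With the lymphocyte score the median was −0.439, a kept share of 0.787 (camera adjusted p = 4.59e-27, adjusted p = 0.00871 with an estimated correlation). That share missed a first bound of 0.8 and met a later one of 0.5, so lymphocytes are argued against only as the whole cause. With the brown-adipocyte score the median was −0.216, a kept share of 0.387 (camera adjusted p = 3.24e-13, adjusted p = 0.0864 with an estimated correlation). Less brown fat in the samples on 44% fat may therefore account for part of the fall. Against it as the whole cause, CAST/EiJ female 44% fat replicates 2 and 4 had Ucp1 at 39.2 and 43.6 CPM, within 7.1 to 66.7 CPM on 10% fat, yet Acly at 81.9 and 75.3 CPM against 93.7 to 700 CPM, and brown fat of lower lipogenesis or a change in muscle itself stays open.

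Between CAST/EiJ and C57BL/6J, 53 protein-coding genes differed at least 16-fold, 27 of them lower in CAST/EiJ. A share of 0.491 had a near-identical copy in the table, and in 21 of these 26 genes the difference shrank beyond a factor of 0.5 on the log2 scale when copies were summed. As the whole cause, reads given to such a copy were argued against for 27 genes with no annotated copy at that identity. They were also argued against for 2 genes, Erdr1 and Plac9b, whose sum with copies kept −5.76 ± 0.24 and −3.6 ± 0.14 (SE over libraries). In 11 of 26 the copies moved in mirror, so reads given to a copy may account for those. The amylases Amy2a2 and Amy2a3 rested on 1 library, and the sums of Gbp10 and 9930111J21Rik2 still differed by −2.83 ± 0.24 and −3.57 ± 0.26. In the other genes with a copy, reads given to it cannot be told apart from a real difference, since an abundant copy can outweigh the gene in the sum. Loss of CAST/EiJ reads that differ from the reference genome would lower more genes than it raises, and the share lower was 0.509, against 0.467 of 15 genes in NZO/HlLtJ. That share reached neither of its bounds, real strain differences were not tested separately, and reads would be needed to decide.

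Differences between strains were found by test in the diet effect of 2 genes and the sex difference of 563 genes. The diet effect on fatty acid oxidation differed by −0.117 for CAST/EiJ minus C57BL/6J and 0.172 for NZO/HlLtJ minus CAST/EiJ, and that on lipogenesis by −0.401 for NZO/HlLtJ minus C57BL/6J. These 3 list differences lost their call with an estimated correlation (adjusted p = 0.799, 0.651 and 0.666), and none of their genes passed over the list alone.

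Libraries were regrouped into 35 splits per comparison, the real one included. The smallest share they can give is 1 of 35, and it was not adjusted over the comparisons. The real split alone reached its count for diet in CAST/EiJ (23 genes, highest other 5), NZO/HlLtJ (70, highest other 5) and NZO/HlLtJ females (7, highest other 4). It did so too for sex in C57BL/6J (2606, highest other 1), CAST/EiJ (732, highest other 3) and NZO/HlLtJ (2027, highest other 48). Each of these counts taken alone was unlikely by chance, at 1 of 35, but chance is not excluded. For strain by sex (563, highest other 1), regrouping the sexes also removes the sex difference within each strain. Those splits cannot decide whether the sex difference varies between strains. For the strain pairs, in fits to the compared libraries, the real counts of 3392, 8270 and 7516 stood against highest others of 1, 1 and 0, again 1 of 35 each. Other splits gave as many genes, with the real one counted among them, for diet in C57BL/6J females (1 gene, 8 splits, highest other 30), CAST/EiJ females (3, 2 splits, highest other 26), CAST/EiJ males (1, 4 splits, highest other 1), NZO/HlLtJ males (10, 4 splits, highest other 57) and strain by diet (2, 2 splits, highest other 2). Each of the 35 splits reaches a count of 0, so the splits say nothing of diet in C57BL/6J (0 genes, highest other 1), C57BL/6J males (0, highest other 1) or sex by diet (0, highest other 3). What sets the splits with 30, 26 and 57 genes apart was not tested.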

How the results depend on the processing

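The settings with marker scores in the model and the fit without libraries above the lymphocyte gap were chosen after the results were seen; the others were fixed before the data were examined. The cause was not tested for any change below. Counts for strain pairs and for sex in C57BL/6J and NZO/HlLtJ stayed within 1.5 times their value under every setting run, except without libraries above the lymphocyte gap. That fit holds fewer samples and was not run where CAST/EiJ is compared. It gave 2397 genes for NZO/HlLtJ against C57BL/6J (4432 over all libraries), 423 for sex in C57BL/6J (2606), 1 for diet in NZO/HlLtJ (70), 0 in NZO/HlLtJ females (7), 0 in NZO/HlLtJ males (10), 0 in C57BL/6J females (1) and 1 in C57BL/6J males (0).

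Diet counts moved most. DESeq2 gave 12 in C57BL/6J, 48 in CAST/EiJ, 228 in NZO/HlLtJ, 20 in C57BL/6J females, 23 in CAST/EiJ females, 10 in CAST/EiJ males, 101 in NZO/HlLtJ females, 86 in NZO/HlLtJ males, 18 for strain by diet and 2 for sex by diet. limma gave 3 in C57BL/6J, 4 in C57BL/6J females, 19 in CAST/EiJ females and 2 in CAST/EiJ males. RLE factors gave 1 in C57BL/6J. The stricter filter, with fewer genes tested, gave 1 in C57BL/6J, 109 in NZO/HlLtJ, 1 in CAST/EiJ females, 0 in CAST/EiJ males and 1 for strain by diet. Without the identifier run there were 5 in CAST/EiJ females and 23 in NZO/HlLtJ females. Fits to the compared libraries alone, with fewer samples, gave 2 in C57BL/6J, 3 in NZO/HlLtJ, 1 in CAST/EiJ females, and 0 in each of C57BL/6J females, CAST/EiJ males, NZO/HlLtJ females and NZO/HlLtJ males.

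With the lymphocyte score there were 9 diet genes in C57BL/6J, 35 in CAST/EiJ, 111 in NZO/HlLtJ, 9 in CAST/EiJ females, 14 in NZO/HlLtJ females and 48 in NZO/HlLtJ males, 4 for strain by diet, 1262 for sex in CAST/EiJ and 951 for strain by sex. With the adipocyte score added there were 15 in C57BL/6J, 101 in CAST/EiJ, 4 in C57BL/6J females, 55 in CAST/EiJ females, 27 in CAST/EiJ males, 44 in NZO/HlLtJ females, 43 for strain by diet, 1168 for sex in CAST/EiJ and 1031 for strain by sex. With the brown-adipocyte score there were 1 in C57BL/6J, 36 in CAST/EiJ (14 of the 23, and 21 of the 36 higher), 25 in NZO/HlLtJ (22 of the 70) and 0 in NZO/HlLtJ females.

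With each library left out in turn, diet counts ranged from 0 to 1 in C57BL/6J, 11 to 36 in CAST/EiJ, 19 to 195 in NZO/HlLtJ, 0 to 7 in C57BL/6J females, 0 to 0 in C57BL/6J males, 2 to 16 in CAST/EiJ females, 1 to 2 in CAST/EiJ males, 0 to 22 in NZO/HlLtJ females and 0 to 88 in NZO/HlLtJ males. The ranges were 2 to 4 for strain by diet, 0 to 1 for sex by diet and 473 to 656 for strain by sex. They were 4018 to 5311, 8029 to 8425 and 7955 to 9106 for the strain pairs NZO/HlLtJ against C57BL/6J, CAST/EiJ against C57BL/6J and NZO/HlLtJ against CAST/EiJ. For sex they were 2090 to 2820 in C57BL/6J, 448 to 788 in CAST/EiJ and 1632 to 2225 in NZO/HlLtJ. In these fits, 3437 values of single genes kept their side of the threshold, 256 lost it, 26 gained it and 1 reversed. In fits to the compared libraries alone 46 lost their call, and with the brown-adipocyte score 29 did. With an estimated correlation 47 list results lost their call and 11 kept their side of the threshold, and with fry 26 lost it.

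Directions turned as follows. With the brown-adipocyte score, CAST/EiJ against C57BL/6J gave −0.132 for Ucp1, a member of that score, −0.296 for Acaca, 21.8 for Amy2a3, 10.7 for Amy2a2 and −0.126 for the lipogenesis list, and NZO/HlLtJ against C57BL/6J gave 0.658 for Amy2a3. Amy2a2 gave 1.26 with the lymphocyte and adipocyte scores. Cela1 ranged from −0.0502 to 3.21 for sex in C57BL/6J over the fits with a library left out, the lowest without female 10% fat replicate 1. For diet in NZO/HlLtJ the adipocyte list gave 0.0185 with the adipocyte score and 0.0191 with both scores, since that score holds the list itself. In NZO/HlLtJ females the PPAR list gave −0.15 without genes shared with other lists, and its test pointed down with a median of 0.0133 with the lymphocyte score.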

Other observations

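The tests below were chosen after the results were seen. In NZO/HlLtJ, extracellular matrix genes had changes of opposite sign with diet in the sexes. All 21 measured genes had a higher change in females than in males, 0 passed over all genes and 15 when adjusted over the list alone (median difference 0.677, camera adjusted p = 3.63e-17, adjusted p = 0.291 with an estimated correlation). In females 21 of 21 changes were positive (median 0.282, camera adjusted p = 5.46e-08, adjusted p = 0.919 with an estimated correlation). In males 2 of 21 were positive (median −0.38, camera adjusted p = 3.08e-08, adjusted p = 0.415 with an estimated correlation). The matrix score differed by 0.222 in females, or 0.129 without 10% fat replicate 4, the library with the high lymphocyte score, and 0.135 and 0.144 without 44% fat replicate 1 or 2. It differed by −0.289 in males. In the first run, the only one with both diets within each sex, it differed by 0.373 and −0.362. None passed in either sex, also when adjusted over the list alone. The collagen gene Col6a1 had 0.37 ± 0.13 in females (adjusted p = 0.297) and −0.35 ± 0.14 in males (adjusted p = 0.405), and Col3a1 −0.58 ± 0.21 in males (adjusted p = 0.363), from edgeR with n = 4 and 4 libraries.

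The clock gene Cry2 had 0.33 ± 0.08 on 44% fat in NZO/HlLtJ (adjusted p = 0.0521, higher in 8 of 8 libraries). Among single libraries, C57BL/6J female 10% fat replicate 1 alone held pancreatic transcripts, with Cela1 at 85.2 CPM against at most 1.44 CPM elsewhere. NZO/HlLtJ female 10% fat replicate 1 had Ucp1 at 79 CPM and Acly at 230 CPM.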
